A study of Rattus norvegicus with 174 samples.

How the data were processed

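Gene expression was measured in total RNA of brain, heart, kidney, liver, lung and blood of 33 adult male Sprague-Dawley rats that inhaled phosphine or air, on single-colour Affymetrix rat arrays of perfect-match probes. Per the labels, RNA was purified with RNeasy columns and labelled with biotin by the 3' IVT Plus kit. The deposited values are log2 signals per probe set, which the authors made with RMA (background correction, quantile normalization and summary) and Partek, with versions not given in the sources used here. Whether all tissues were normalized together is not given either. The values run from 1.74 to 14.13 over 31139 probe sets. Arrays have no read depth, so their number limits the precision.

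Of the probe sets, 97 are controls, 19063 list 1 gene, 572 several and 11407 none. Probe sets of 1 gene gave 13438 genes, 9453 with 1 probe set and 3985 with several, for which the probe set with the highest mean over all arrays was used. Positions were taken from the reference assembly GRCr8 and used only to find neighbouring genes. No dim gene was left out. Each tissue was fitted with limma 3.58.1 (R 4.3.3 and the data.table package, version 1.17.8) with a mean per group of exposure and time. Contrasts of phosphine minus air at the same time were tested with eBayes, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The spread was estimated over all arrays of the tissue, so that the 6 h comparisons, with 2 air rats or 1 air blood sample, could be tested. Differences of the effect between times, and between the 5 solid tissues at a time, were tested with limma's moderated F. Genes were called shared when they changed the same way in at least 3 of 5 tissues. RNA integrity was compared by two-sided exact permutation tests of the 3' minus 5' log2 difference of control transcripts. Figures were drawn with python 3.11.15.

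The comparisons, alternatives, gene lists and the rule for named genes were chosen before the data were examined. The 47 lists, 26 by function and 21 of cell type markers, were tested with camera. The rule took, per comparison, up to 8 called genes with the largest rise and 8 with the largest fall whose higher group mean lay above the median of all probe sets (4.41). It added up to 4 called members per list, the panel Hmox1, Mt2A, Hspa1b, Ddit3, Fkbp5, Fos, Lcn2 and Il1b, 5 genes per test of a difference and 10 shared genes per time. Hspa1b and Fos have no probe set of their own and were not analysed here. The rule named 708 pairs of a gene and a comparison, and 246 are printed, picked from these after their values were seen.

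Alternatives were quantile normalization within tissue, array median centring, leaving out genes under the 40th percentile, the mean of probe sets per gene, eBayes with trend and robust fit, array quality weights, only the 2 groups in the fit, air of all times pooled, the rat as a block, a preset correlation of 0.01 for lists, and leaving out each rat. Chosen after the data were seen were leaving out 10 arrays with transcripts of another organ, the 75th percentile of the array as covariate in blood, and leaving out each rat for the tests of differences and the shared genes. Other splits of the same rats were run where both groups had at least 3. The method was tested on simulated data with 200 changed genes. At a fold of 2 it recovered from 68.7% (liver 6 h) to 98.5% of them in solid tissues, and in blood 16.4% at 1 h, 13.4% at 3 h and 0% at 6 h. Of its calls, from 0% to 9.1% were of unchanged genes. The 2 blood samples at 24 h were given as values.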

Results

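The 33 rats, of an outbred stock, inhaled phosphine, a toxic fumigant gas, or air. The labels give 660 ppm for 32.2 min, a product of 21252 ppm x min or 0.91 times the median lethal product (LCt50). Brain, heart, kidney, liver and lung were taken 1, 3, 6 and 24 h later. Each solid-tissue group had 4 rats, except that the 6 h air groups had 2. The 5 solid tissues of a group came from the same rats. Blood had 4 exposed and 4 air samples at 1 and 3 h, 5 exposed and 1 air sample at 6 h, and 2 exposed samples with no air sample at 24 h. Each comparison tested 13438 genes. Changes are given as log2 phosphine minus air ± the SE of the limma fit, so that 1 is a 2-fold difference, and padj is the Benjamini-Hochberg adjusted p. Gene lists were tested with camera, whose padj is given with an estimated correlation of the members, beside calls among its measured members, in brackets adjusted over the list. For a called list, runs are the alternative settings and left-out rats, with the highest padj among them. The chance share beside groups that do not overlap is that of a gene not picked, so for called genes it is no test. For Per2 (3 h), Foxo1 (1 and 3 h), Edem1 (3 h) and Fkbp5 (6 h) in liver, Fkbp5 in blood at 6 h, Srxn1 in kidney at 3 h, and Adamts9 (1 h) and Nr4a3 (3 h) in lung, 1 other probe set had the opposite sign. Left-out rats, and the settings with the lowest and highest count, are named where they moved a count by more than 1.5 times.

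Control probe sets gave the log2 difference between 3' and 5' ends of control transcripts, which is higher in less intact RNA. In two-sided exact permutation tests (23 comparisons), 4 against 4 rats allow no p under 0.0286, 4 against 2 none under 0.0667 and blood at 6 h none under 0.167, so that no comparison alone could pass the adjustment. The smallest p was reached in brain at 3 h (-0.155, padj = 0.329), liver at 1 h (-0.147, padj = 0.329), kidney at 6 h (0.114, padj = 0.394) and blood at 6 h (-0.301, padj = 0.639). On 10 solid-tissue arrays, 8 of exposed and 2 of air rats, the mean of a marker list of another organ or of muscle lay at least 4 log2 above the median of the tissue. They are given with their groups, except for the liver of exposed Rat741 at 24 h, where distal nephron genes stood 4.43 higher.

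**Figure D1:**
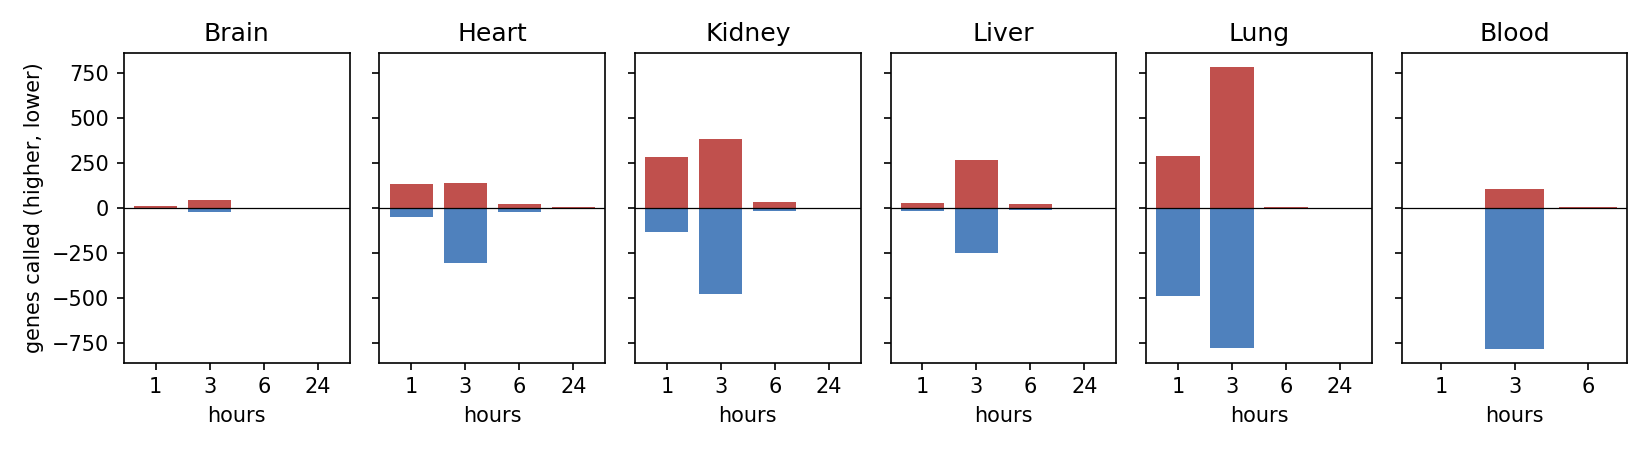
Number of genes called by limma (adjusted p under 0.05) in each tissue against hours after exposure. Bars above 0 count genes higher and bars below 0 genes lower in phosphine than in air rats. The highest count is 1559 in lung at 3 h, and no solid tissue has more than 11 genes at 24 h.

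In brain at 1 h the largest rises were of Tmem252 (2.23 ± 0.18, padj = 2.59e-08), Pdk4 (1.65 ± 0.29, padj = 0.00708), a kinase that inhibits pyruvate dehydrogenase, and Sgk1 (1.31 ± 0.27, padj = 0.0404), a kinase induced by glucocorticoids. The cell cycle inhibitor Cdkn1a (0.99 ± 0.16, padj = 0.0038) and the glucose transporter Slc2a1 (0.59 ± 0.09, padj = 0.0038) also rose. G0s2, an inhibitor of triglyceride breakdown (-1.11 ± 0.12, padj = 6.93e-06), Tnfrsf11b (-0.94 ± 0.19, padj = 0.0248) and the tight junction gene Ocln (-0.53 ± 0.10, padj = 0.0105) fell. Of the glucocorticoid responsive genes, 3 of 20 were higher and 0 lower (11 and 0 over the list, padj = 0.242 with an estimated correlation). Limma called 20 genes (n = 4 exposed and 4 air), 15 higher and 5 lower, 4 of them at least 2-fold. In 9 of 9 called genes named groups did not overlap (chance share 2.86%). The count was 9 without Rat721, 11 without Rat719 and 70 without Rat710, and by setting 1 (only the 2 groups) to 382 (array weights).

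In brain at 3 h 7 of 20 glucocorticoid responsive genes were higher and 0 lower (13 and 0 over the list, padj = 0.0194, lost in 2 of 17 runs, up to 0.369), with Pdk4 (1.92 ± 0.29, padj = 7.49e-04), Sgk1 (1.41 ± 0.27, padj = 0.00883) and Fkbp5, a co-chaperone of the glucocorticoid receptor (1.13 ± 0.15, padj = 1.36e-04), higher. Of the endothelial markers, 0 of 9 were higher and 1 lower (0 and 5 over the list, padj = 0.00483, lost in 2 of 17 runs, up to 0.35), with Emcn (-0.74 ± 0.14, padj = 0.00663) lower. Mt2A, a metal-binding metallothionein (1.34 ± 0.23, padj = 0.00271), and Slc2a1 (1.02 ± 0.09, padj = 3.81e-07) rose, as did Tmem252 (1.64 ± 0.18, padj = 8.92e-06), Pla2g3 (1.44 ± 0.21, padj = 4.91e-04) and the macrophage gene Mrc1 (0.78 ± 0.15, padj = 0.00583). Falls included Rnase4 (-2.11 ± 0.46, padj = 0.0268), Prom1 (-0.79 ± 0.10, padj = 1.36e-04), the blood-brain barrier transporter Slco1a4 (-0.76 ± 0.09, padj = 6.14e-05) and Vegfa (-0.43 ± 0.08, padj = 0.00942), a growth factor of vessels. Of the hypoxia list 2 of 21 were higher and 1 lower (2 and 2 over the list, padj = 0.534). Limma called 68 genes (n = 4 exposed and 4 air), 49 higher and 19 lower, 18 of them at least 2-fold. In 15 of 16 called genes named groups did not overlap (chance share 2.86%). The 3' minus 5' difference was lower in all 4 exposed rats (0.359 against 0.514, more intact). The count was 40 without Rat730 and 42 without Rat738, and by setting 150 (array weights).

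At 6 and 24 h limma called 0 brain genes, with 5.64% and 3.79% of genes at an unadjusted p under 0.05. The largest panel value at 6 h was that of Mt2A (1.28 ± 0.29, padj = 0.252, n = 4 exposed and 2 air rats), and at 24 h that of Fkbp5 (0.16 ± 0.15, padj = 0.9997, n = 4 and 4), neither past the threshold. The 6 h count was 2 without Rat762 and 3 without Rat763, and by setting 2 (only the 2 groups) to 20 (pooled air).

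In heart at 1 h 15 of 24 immediate early genes were higher and 0 lower (22 and 0 over the list, padj = 0.0228, lost in 3 of 18 runs, up to 0.152), which follow a stimulus first. They include Fosb (2.89 ± 0.67, padj = 0.0277), Nr4a1 (3.11 ± 0.58, padj = 0.0044), Nr4a3 (2.46 ± 0.39, padj = 8.23e-04), Egr1 (2.23 ± 0.54, padj = 0.0355) and Ccn1 (3.46 ± 0.75, padj = 0.0187). Of the ATF4 list, genes of the integrated stress response, 6 of 24 were higher and 0 lower (8 and 0 over the list, padj = 0.031, lost in 7 of 18 runs, up to 0.425), led by Atf3 (4.16 ± 0.57, padj = 3.09e-04) and Gdf15 (2.19 ± 0.51, padj = 0.0285). Of the coagulation and matrix list, 6 of 16 were higher and 0 lower (7 and 0 over the list, padj = 0.031, lost in 7 of 18 runs, up to 0.364), with Adamts1 (1.72 ± 0.29, padj = 0.00155), Plaur (1.58 ± 0.35, padj = 0.0192) and tissue factor F3 (1.22 ± 0.22, padj = 0.00357). Of the glucocorticoid responsive genes, 4 of 20 were higher and 0 lower (10 and 0 over the list, padj = 0.0228, lost in 3 of 18 runs, up to 0.29), among them Gadd45b (2.44 ± 0.37, padj = 6.23e-04) and Sgk1 (1.71 ± 0.31, padj = 0.00346). Falls included the apelin receptor Aplnr (-2.36 ± 0.37, padj = 7.21e-04) and the chemokine receptor Cxcr4 (-1.31 ± 0.27, padj = 0.0104), while the endothelial markers Cldn5 (1.14 ± 0.26, padj = 0.0255) and Flt1 (0.92 ± 0.22, padj = 0.0358) rose. Hepatocyte markers stood 3.69 above the heart median on the array of exposed Rat712, under the limit of 4. Limma called 179 genes (n = 4 exposed and 4 air), 133 higher and 46 lower, 72 of them at least 2-fold. Of those called, genes higher were 95 of 151 with quantile normalization and 81 of 132 with median centring. In 19 of 19 called genes named groups did not overlap (chance share 2.86%). The count was 73 without Rat712, 78 without Rat721, 79 without Rat719 and 115 without Rat726. It was 119 without Rat720, and by setting 51 (only the 2 groups) to 547 (pooled air).

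In heart at 3 h Atf3 (4.43 ± 0.57, padj = 1.36e-04) and Nr4a3 (3.98 ± 0.39, padj = 3.49e-06) were higher. Angptl4, an inhibitor of lipoprotein lipase (2.87 ± 0.57, padj = 0.0054), Mt2A (2.86 ± 0.56, padj = 0.0054), the heme-degrading enzyme Hmox1 (1.71 ± 0.37, padj = 0.01) and Fkbp5 (2.0 ± 0.23, padj = 2.75e-05) rose. Of the clock genes 0 of 16 were higher and 5 lower (0 and 5 over the list, padj = 0.238 with an estimated correlation), with Dbp (-1.87 ± 0.36, padj = 0.00513), Nr1d2 (-0.94 ± 0.17, padj = 0.00308) and Bhlhe41 (-1.01 ± 0.23, padj = 0.0172). Of the macrophage markers 5 of 12 were higher and 0 lower (5 and 0 over the list, padj = 0.238 with an estimated correlation), with Cd163 (1.01 ± 0.27, padj = 0.0382) and Mrc1 (0.89 ± 0.15, padj = 0.00216). Among glucocorticoid responsive genes 5 of 20 were higher and 0 lower (10 and 0 over the list, padj = 0.0556 with an estimated correlation). Of the ATF4 list 3 of 24 were higher and 0 lower (5 and 1 over the list, padj = 0.056 with an estimated correlation). Falls included Hs3st5 (-1.96 ± 0.42, padj = 0.00967), Ky (-1.68 ± 0.21, padj = 7.93e-05), which muscle expresses, the gap junction gene Gja1 (-0.84 ± 0.11, padj = 1.51e-04) and Emcn (-0.63 ± 0.14, padj = 0.0116). On 1 of the 4 exposed arrays, that of Rat729, hepatocyte markers stood 8.32 above the heart median. Limma called 448 genes (n = 4 exposed and 4 air), 142 higher and 306 lower, 112 of them at least 2-fold. In 16 of 17 called genes named groups did not overlap (chance share 2.86%). The count was 187 without Rat739, 203 without Rat738, 230 without Rat729 and 249 without Rat730. It was 265 without Rat731, 274 without Rat733, 297 without Rat732 and 1099 without Rat728, and by setting 13 (only the 2 groups) to 1072 (pooled air).

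In heart at 6 h the muscle gene Klhl40 (3.31 ± 0.68, padj = 0.0249), Angptl4 (3.07 ± 0.69, padj = 0.0486) and the chemokine Ccl2 (3.06 ± 0.68, padj = 0.0458) rose. The TWEAK receptor Tnfrsf12a (2.46 ± 0.38, padj = 0.00472), Ankrd2 (2.29 ± 0.44, padj = 0.0191) and the endothelial adhesion gene Sele (2.08 ± 0.37, padj = 0.0138) rose too. Of the fatty acid oxidation list 3 of 26 were higher and 0 lower (4 and 0 over the list, padj = 0.382 with an estimated correlation), with Pdk4 (1.98 ± 0.24, padj = 2.76e-04) and the mitochondrial carrier Ucp3 (1.79 ± 0.37, padj = 0.0249). The cytoskeletal gene Flnc (1.20 ± 0.25, padj = 0.0274) rose, and Alkbh2 (-1.39 ± 0.25, padj = 0.0177) and Ptpn13 (-1.08 ± 0.21, padj = 0.0206) fell. Hepatocyte markers stood 4.07 above the heart median on the array of exposed Rat760. Limma called 47 genes (n = 4 exposed and 2 air), 25 higher and 22 lower, 23 of them at least 2-fold. Of those called, genes higher were 27 of 35 with quantile normalization and 29 of 34 with median centring. In 12 of 12 called genes named groups did not overlap (chance share 13.3%). The count was 3 without Rat762 or Rat763, 11 without Rat761 and 27 without Rat789, and by setting 4 (only the 2 groups) to 794 (pooled air).

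In heart at 24 h, the nicotinamide riboside kinase Nmrk2 (3.36 ± 0.38, padj = 3.19e-05), osteopontin Spp1 (3.06 ± 0.48, padj = 0.00431) and Gpnmb (2.78 ± 0.31, padj = 3.19e-05) were the largest rises. Of the macrophage markers 1 of 12 was higher and 0 lower (5 and 0 over the list, padj = 0.0349, lost in 8 of 18 runs, up to 0.254), with Cd68 (1.27 ± 0.23, padj = 0.0157). The myeloid receptors Lilrb4 (1.81 ± 0.27, padj = 0.0028) and Clec7a (1.51 ± 0.30, padj = 0.0457) and the actin gene Acta1 (0.76 ± 0.13, padj = 0.0133) also rose, and Rab3b (-1.05 ± 0.21, padj = 0.0457) fell. Hepatocyte genes on the array of Rat741 stood 8.02 and alveolar genes on that of Rat749 4.58 above the heart median, and both rats were exposed. Without these 2 arrays the macrophage list had a padj of 0.108. Limma called 11 genes (n = 4 exposed and 4 air), 10 higher and 1 lower, 9 of them at least 2-fold. Of those called, genes higher were 7 of 10 with median centring. In 8 of 8 called genes named groups did not overlap (chance share 2.86%). The count was 4 without Rat744 or Rat749, 5 without Rat745, 6 without Rat742, Rat750 or Rat751 and 32 without Rat741, and by setting 0 (only the 2 groups) to 260 (array weights).

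**Figure D2:**
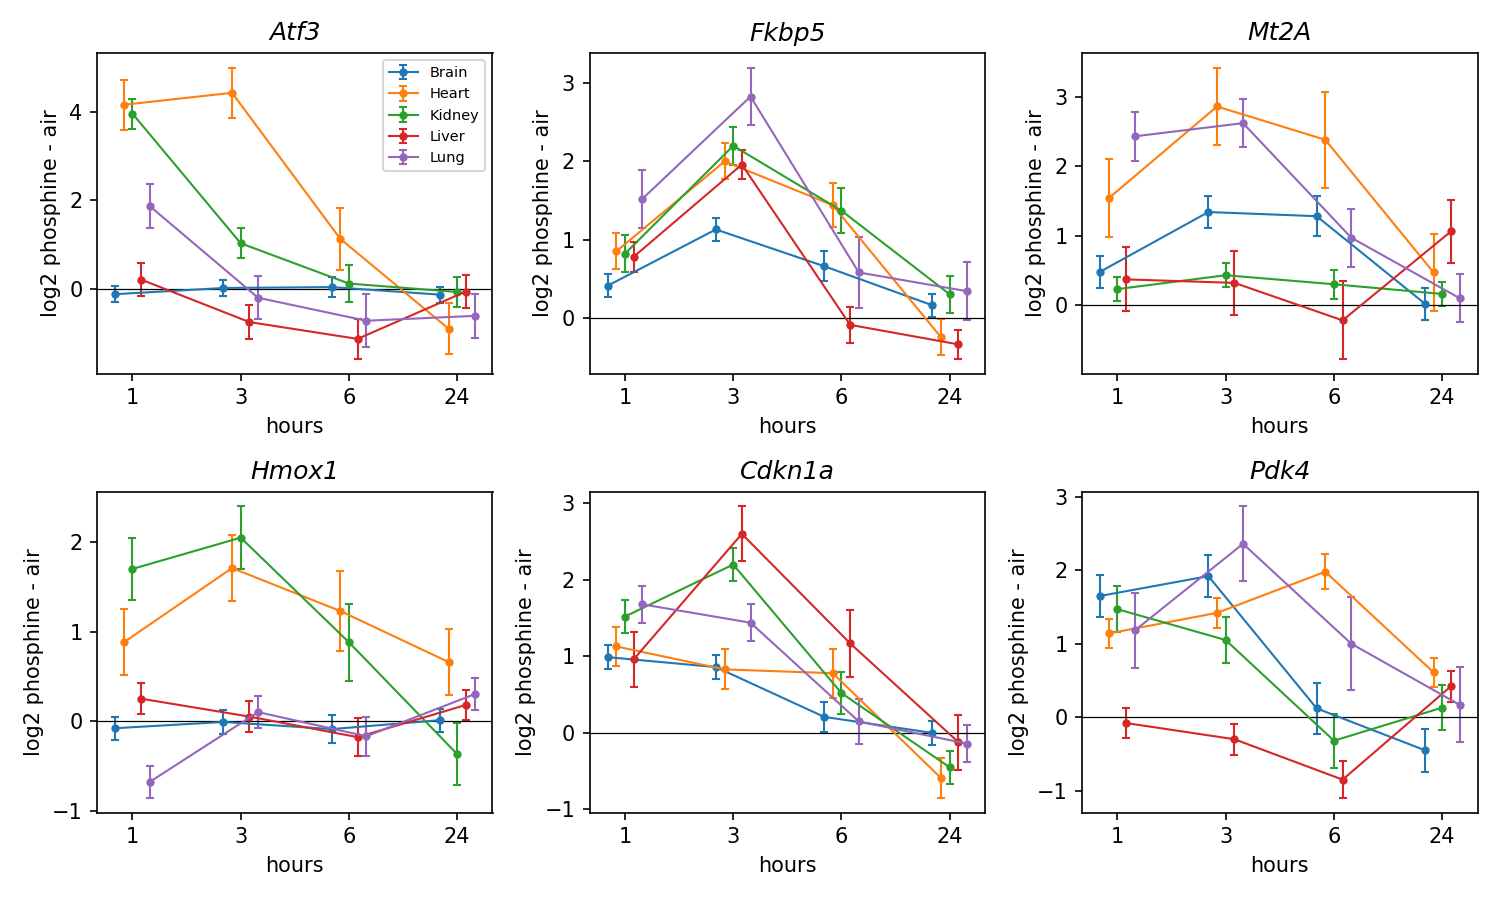
Log2 phosphine minus air (mean difference, bars ± SE of the limma fit) against hours after exposure for Atf3, Fkbp5, Mt2A, Hmox1, Cdkn1a and Pdk4 in the 5 solid tissues. Fkbp5 is higher in all 5 tissues at 3 h, from 1.13 in brain to 2.83 in lung.

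In kidney at 1 h 12 of 24 immediate early genes were higher and 0 lower (18 and 0 over the list, padj = 0.0338, lost in 9 of 18 runs, up to 0.0929), with Fosb (3.27 ± 0.33, padj = 5.59e-07) and Nr4a1 (2.51 ± 0.35, padj = 1.02e-04). Of the ATF4 list 6 of 24 were higher and 0 lower (7 and 0 over the list, padj = 0.0338, lost in 8 of 18 runs, up to 0.12), with Atf3 (3.96 ± 0.34, padj = 1.07e-07), Gdf15 (2.39 ± 0.23, padj = 2.65e-07) and Cebpb (1.37 ± 0.23, padj = 8.93e-04). Hmox1 (1.7 ± 0.35, padj = 0.00695), Ddit3, a transcription factor of the unfolded protein response (0.93 ± 0.14, padj = 4.43e-04), Cdkn1a (1.52 ± 0.22, padj = 1.35e-04) and the clock gene Nfil3 (1.66 ± 0.15, padj = 2.07e-07) rose. Among glucocorticoid responsive genes 8 of 20 were higher and 0 lower (13 and 0 over the list, padj = 0.105 with an estimated correlation). Of the clock genes 4 of 16 were higher and 0 lower (6 and 0 over the list, padj = 0.105 with an estimated correlation). The chemokines Ccl2 (-1.32 ± 0.33, padj = 0.0275) and Ccl4 (-0.94 ± 0.21, padj = 0.0133) and Indian hedgehog Ihh (-1.39 ± 0.25, padj = 0.00161) fell. Of the p53 targets 3 of 17 were higher and 0 lower (3 and 0 over the list, padj = 0.105 with an estimated correlation). Hepatocyte markers stood 5.07 above the kidney median on the array of air Rat720. Limma called 419 genes (n = 4 exposed and 4 air), 285 higher and 134 lower, 45 of them at least 2-fold. In 15 of 15 called genes named groups did not overlap (chance share 2.86%). The count was 193 without Rat719, 209 without Rat721 and 245 without Rat720, and by setting 39 (only the 2 groups) to 245 (the other-organ arrays left out).

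In kidney at 3 h Tnfrsf12a (2.49 ± 0.19, padj = 3.35e-09), Tmem252 (2.32 ± 0.21, padj = 5.24e-08), Fkbp5 (2.20 ± 0.24, padj = 2.26e-06), Cdkn1a (2.20 ± 0.22, padj = 3.61e-07) and the tight junction gene Cldn4 (1.53 ± 0.18, padj = 7.14e-06) rose. Of the NRF2 targets, genes of the antioxidant response, 5 of 19 were higher and 0 lower (5 and 0 over the list, padj = 0.211 with an estimated correlation), with Hmox1 (2.05 ± 0.35, padj = 5.94e-04), the sulfiredoxin Srxn1 (1.63 ± 0.37, padj = 0.00676) and the exporter Abcc2 (1.23 ± 0.22, padj = 7.85e-04). Of the ATF4 list 6 of 24 were higher and 0 lower (8 and 0 over the list, padj = 0.0728 with an estimated correlation), with Gdf15 (1.72 ± 0.23, padj = 3.05e-05), Ddit3 (1.54 ± 0.14, padj = 1.58e-07) and Atf4 (0.77 ± 0.09, padj = 5.17e-06). Of the glucocorticoid responsive genes 5 of 20 were higher and 0 lower (11 and 0 over the list, padj = 0.36 with an estimated correlation). Of the hypoxia list 2 of 21 were higher and 2 lower (6 and 4 over the list, padj = 0.898), with a rise of Slc2a1 (0.80 ± 0.11, padj = 5.34e-05) and a fall of Ankrd37 (-0.52 ± 0.10, padj = 0.00192). Falls included Ihh (-1.43 ± 0.25, padj = 6.37e-04), Ccl2 (-1.33 ± 0.33, padj = 0.0143), A4galt (-1.29 ± 0.20, padj = 1.76e-04), the clock gene Dbp (-1.23 ± 0.26, padj = 0.0037) and the vasopressin receptor of the collecting duct, Avpr2 (-0.73 ± 0.12, padj = 4.13e-04). Limma called 859 genes (n = 4 exposed and 4 air), 384 higher and 475 lower, 59 of them at least 2-fold. Of those called, genes higher were 516 of 862 with median centring. In 22 of 23 called genes named groups did not overlap (chance share 2.86%). For kidney 3 h, settings that moved it gave 463 (only the 2 groups) and 1777 (pooled air).

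In kidney at 6 h Tnfrsf12a (2.17 ± 0.23, padj = 5.09e-06), Gdf15 (2.07 ± 0.28, padj = 3.14e-04), the lipoprotein receptor Scarb1 (1.78 ± 0.13, padj = 1.99e-09), Fkbp5 (1.37 ± 0.29, padj = 0.0318) and Slc2a1 (0.67 ± 0.14, padj = 0.0208) rose. The cytochrome P450 reductase Por (0.70 ± 0.12, padj = 0.00838) and the water channel Aqp3 (0.61 ± 0.13, padj = 0.0347) rose, and the vessel growth factor Angpt1 (-1.17 ± 0.22, padj = 0.0141) fell. The 3' minus 5' difference was higher in all 4 exposed rats (0.707 against 0.594, less intact). Limma called 47 genes (n = 4 exposed and 2 air), 34 higher and 13 lower, 9 of them at least 2-fold. In 8 of 8 called genes named groups did not overlap (chance share 13.3%). The count was 3 without Rat763, 4 without Rat762, 16 without Rat761 and 24 without Rat789, and by setting 7 (only the 2 groups) to 1676 (pooled air). At 24 h limma called 0 kidney genes, with 5.5% of genes at an unadjusted p under 0.05, and the panel genes lay between Hmox1 (-0.37 ± 0.35, padj = 0.967) and Fkbp5 (0.30 ± 0.24, padj = 0.967).

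In liver at 1 h the rises included Ppargc1a, a coactivator of mitochondrial and gluconeogenic genes (2.56 ± 0.42, padj = 0.00644), Coq10b (2.07 ± 0.35, padj = 0.00725) and Ppargc1b (1.57 ± 0.26, padj = 0.00698). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (1.36 ± 0.26, padj = 0.0119), and the transcription factor Foxo1 (1.17 ± 0.25, padj = 0.0257) rose. Osgin1 (-2.07 ± 0.39, padj = 0.0119), Rsrp1 (-1.47 ± 0.19, padj = 7.76e-04) and the chaperone Hspa8 (-0.66 ± 0.14, padj = 0.0262) fell. As sets, 0 of 20 glucocorticoid responsive genes were higher and 0 lower (7 and 0 over the list, padj = 0.0227, lost in 5 of 18 runs, up to 0.103) and 0 of 24 genes of the ATF4 list were higher and 0 lower (2 and 0 over the list, padj = 0.0274, lost in 7 of 18 runs, up to 0.213). The 3' minus 5' difference was lower in exposed rats (0.483 against 0.630). Skeletal muscle markers stood 5.56 above the liver median on the array of exposed Rat719. Limma called 45 genes (n = 4 exposed and 4 air), 28 higher and 17 lower, 18 of them at least 2-fold. In 8 of 8 called genes named groups did not overlap (chance share 2.86%). The count was 9 without Rat720, 16 without Rat719, 19 without Rat712 and 20 without Rat721, and by setting 8 (only the 2 groups) to 243 (pooled air).

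In liver at 3 h Ppargc1a (3.71 ± 0.42, padj = 1.06e-05), the lysolipid transporter Mfsd2a (2.64 ± 0.45, padj = 7.45e-04), Cdkn1a (2.60 ± 0.36, padj = 7.29e-05), Coq10b (2.31 ± 0.35, padj = 2.44e-04) and Fkbp5 (1.96 ± 0.19, padj = 1.32e-06) rose. Of the glucocorticoid responsive genes 3 of 20 were higher and 1 lower (5 and 1 over the list, padj = 0.854 with an estimated correlation), with the serine-degrading enzyme Sds (1.83 ± 0.31, padj = 5.89e-04) and Per1 (1.38 ± 0.36, padj = 0.0257) higher and Dusp1 (-1.44 ± 0.42, padj = 0.0493) lower. Of the clock genes 1 of 16 was higher and 3 lower (1 and 6 over the list, padj = 0.854), the falls being of Per2 (-1.77 ± 0.35, padj = 0.00324), Bhlhe40 (-1.71 ± 0.44, padj = 0.0253) and Nr1d2 (-0.79 ± 0.19, padj = 0.0143). The acute phase gene Lcn2 (1.19 ± 0.30, padj = 0.0238), the unfolded protein response gene Edem1 (1.26 ± 0.18, padj = 1.47e-04), Por (1.39 ± 0.19, padj = 6.01e-05) and Foxo1 (1.23 ± 0.25, padj = 0.00333) rose. Osgin1 (-2.31 ± 0.39, padj = 5.89e-04), Mid1ip1 (-1.94 ± 0.26, padj = 5.00e-05), the phosphatase Dusp6 (-1.85 ± 0.37, padj = 0.00329) and the chaperone Dnaja1 (-0.72 ± 0.11, padj = 1.47e-04) fell. Limma called 518 genes (n = 4 exposed and 4 air), 267 higher and 251 lower, 122 of them at least 2-fold. In 19 of 20 called genes named groups did not overlap (chance share 2.86%). The count was 308 without Rat738, 327 without Rat732, 331 without Rat730 and 333 without Rat739, and by setting 260 (only the 2 groups) to 1007 (array weights).

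In liver at 6 h Cux2 (2.22 ± 0.46, padj = 0.0353), the aspartate aminotransferase Got1 (1.46 ± 0.22, padj = 0.0079) and Edem1 (1.07 ± 0.23, padj = 0.0353) rose. Timm9 (0.98 ± 0.19, padj = 0.027) and Tomm40 (0.97 ± 0.19, padj = 0.027), of mitochondrial protein import, and Cox10 (0.94 ± 0.17, padj = 0.0171), of cytochrome c oxidase assembly, rose. Chodl (-1.63 ± 0.34, padj = 0.0353), Txnrd3 (-0.97 ± 0.20, padj = 0.0318) and Rarres1 (-0.95 ± 0.16, padj = 0.0154) fell. Limma called 30 genes (n = 4 exposed and 2 air), 22 higher and 8 lower, 5 of them at least 2-fold. In 9 of 9 called genes named groups did not overlap (chance share 13.3%). The count was 0 without Rat762 or Rat763, 2 without Rat761, 11 without Rat789 and 12 without Rat760. It was 58 without Rat758, and by setting 0 (only the 2 groups) to 969 (pooled air). At 24 h limma called 0 liver genes, with 7.14% at an unadjusted p under 0.05, and the largest panel value was that of Mt2A (1.06 ± 0.46, padj = 0.672).

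In lung at 1 h Fosb (3.14 ± 0.44, padj = 4.81e-05), Nr4a3 (2.80 ± 0.25, padj = 2.75e-07), Mt2A (2.43 ± 0.35, padj = 5.95e-05), Creb5 (2.16 ± 0.26, padj = 1.00e-05) and Crem (2.04 ± 0.21, padj = 1.39e-06) were the largest rises. Of the coagulation and matrix list 4 of 16 were higher and 1 lower (6 and 1 over the list, padj = 0.00732, lost in 2 of 18 runs, up to 0.194), with Adamts9 (1.58 ± 0.18, padj = 3.23e-06), Adamts1 (1.5 ± 0.23, padj = 1.42e-04) and the plasminogen activator Plat (1.14 ± 0.15, padj = 1.72e-05) higher. Of the ATF4 list 3 of 24 were higher and 0 lower (5 and 0 over the list, padj = 0.0422, lost in 10 of 18 runs, up to 0.283), with Atf3 (1.87 ± 0.49, padj = 0.0199). Of the cholesterol synthesis list 3 of 19 were higher and 0 lower (4 and 0 over the list, padj = 0.362 with an estimated correlation). Of the glucocorticoid responsive genes 4 of 20 were higher and 0 lower (5 and 0 over the list, padj = 0.116 with an estimated correlation). Il1a (1.81 ± 0.46, padj = 0.0163), Tnfaip6 (1.32 ± 0.23, padj = 7.08e-04) and the chaperone Hspa1a (1.61 ± 0.19, padj = 5.50e-06) rose. Fam13c (-1.46 ± 0.18, padj = 1.10e-05), Ccl2 (-1.40 ± 0.40, padj = 0.0359), Meox2 (-1.37 ± 0.19, padj = 5.25e-05), the sphingosine phosphate transporter Spns2 (-1.32 ± 0.13, padj = 1.09e-06), Lcn2 (-1.33 ± 0.33, padj = 0.0132) and Hmox1 (-0.68 ± 0.18, padj = 0.0235) fell. Hepatocyte markers stood 7.79 above the lung median on the array of exposed Rat716. Limma called 779 genes (n = 4 exposed and 4 air), 293 higher and 486 lower, 76 of them at least 2-fold. In 18 of 21 called genes named groups did not overlap (chance share 2.86%). For lung 1 h, settings that moved it gave 132 (only the 2 groups) and 1831 (pooled air).

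In lung at 3 h Fkbp5 (2.83 ± 0.37, padj = 1.47e-05), Mt2A (2.62 ± 0.35, padj = 1.72e-05), Pdk4 (2.36 ± 0.51, padj = 0.00295) and Il1r2, a decoy receptor of interleukin 1 (2.11 ± 0.26, padj = 8.36e-06), rose. Among glucocorticoid responsive genes 8 of 20 were higher and 0 lower (11 and 0 over the list, padj = 0.122 with an estimated correlation). Of the ATF4 list 7 of 24 were higher and 1 lower (8 and 1 over the list, padj = 0.07 with an estimated correlation). Of the fatty acid oxidation list 6 of 26 were higher and 0 lower (8 and 0 over the list, padj = 0.45 with an estimated correlation). Of the neutrophil markers 5 of 9 were higher and 1 lower (5 and 1 over the list, padj = 0.255 with an estimated correlation), with S100a9 (1.36 ± 0.23, padj = 3.66e-04) and Pglyrp1 (1.29 ± 0.25, padj = 9.77e-04) higher. Of the macrophage markers 6 of 12 were higher and 2 lower (6 and 2 over the list, padj = 0.255), with C1qb (0.89 ± 0.14, padj = 1.07e-04) and Cd14 (0.82 ± 0.15, padj = 5.99e-04) higher. Of the T and NK lymphocyte markers 0 of 15 were higher and 4 lower (0 and 4 over the list, padj = 0.45 with an estimated correlation), with Gzmb (-1.36 ± 0.37, padj = 0.0175) and Cd8a (-0.76 ± 0.20, padj = 0.0136).

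Falls in lung at 3 h included the B cell scaffold Bank1 (-2.03 ± 0.18, padj = 5.18e-07), the receptor Bmpr2 (-1.53 ± 0.25, padj = 2.15e-04) and the vessel growth factor receptor Kdr (-0.94 ± 0.10, padj = 1.94e-06). The endothelial genes Cldn5 (0.63 ± 0.12, padj = 6.52e-04) and Esam (0.33 ± 0.09, padj = 0.0128) rose. Of the endothelial markers 2 of 9 were higher and 2 lower (3 and 3 over the list, padj = 0.902, mean -0.04, median 0.05, test down). Of the respiratory chain list 5 of 26 were higher and 0 lower (7 and 0 over the list, padj = 0.712 with an estimated correlation), with Cyc1 (0.54 ± 0.14, padj = 0.00984). The cytokine Il1b (0.82 ± 0.24, padj = 0.0265) and the water channel Aqp1 (1.11 ± 0.13, padj = 6.47e-06) rose. Among RT1 genes, the rat's major histocompatibility genes, RT1-CE16 (3.15 ± 0.82, padj = 0.0128) rose and RT1-T24-3 (-2.40 ± 0.58, padj = 0.00734), RT1-CE5 (-2.12 ± 0.62, padj = 0.0255) and RT1-N2 (-1.70 ± 0.47, padj = 0.0204) fell. RT1-CE16 also differed among air rats, from 3.26 to 5.59 as the mean of 5 tissues. Skeletal muscle markers stood 5.78 above the lung median on the array of exposed Rat729 and 6.79 on that of air Rat733. Limma called 1559 genes (n = 4 exposed and 4 air), 785 higher and 774 lower, 141 of them at least 2-fold. In 22 of 25 called genes named groups did not overlap (chance share 2.86%). The count was 913 without Rat730.

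In lung at 6 h the neuropeptide gene Gal (2.35 ± 0.39, padj = 0.0112), Crispld2 (1.32 ± 0.18, padj = 0.00112) and Adam15 (0.84 ± 0.13, padj = 0.00396) rose, and Plcb1 (-1.22 ± 0.24, padj = 0.0418) and the endothelial gene Emcn (-0.92 ± 0.16, padj = 0.0112) fell. Limma called 13 genes (n = 4 exposed and 2 air), 8 higher and 5 lower, 4 of them at least 2-fold. In 5 of 5 called genes named groups did not overlap (chance share 13.3%). The count was 3 without Rat761 or Rat763, 6 without Rat789, 7 without Rat762 and 25 without Rat758. It was 39 without Rat760, and by setting 0 (only the 2 groups) to 429 (pooled air).

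In lung at 24 h the clock repressor Nr1d2 (1.04 ± 0.16, padj = 0.0158, n = 4 and 4) was the 1 gene called, with 424 genes at an unadjusted p under 0.05. Its 4 exposed values lay above all 4 air values (chance share 2.86%). Of the cell cycle genes 0 of 27 were higher and 0 lower (0 and 13 over the list, padj = 0.0469, lost in 12 of 18 runs, up to 0.227). Of the clock genes 1 of 16 was higher and 0 lower (6 and 2 over the list, padj = 0.0469, lost in 13 of 18 runs, up to 0.921). Of the T and NK lymphocyte markers 0 of 15 were higher and 0 lower (1 and 0 over the list, padj = 0.0469, lost in 13 of 18 runs, up to 0.247). Means were negative for neutrophil markers (-0.42, padj = 0.087) and red blood cell markers (-0.26, padj = 0.087), neither called. The count was 0 without Rat742, Rat744, Rat748, Rat749, Rat750 or Rat751 and 2 without Rat745, and by setting 0 (the mean of probe sets or pooled air) to 11 (only the 2 groups).

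In blood at 1 h limma called 1 gene, the laminin gene Lamb2 (2.21 ± 0.35, padj = 0.0259), higher in 4 of 4 exposed rats than in all 4 air rats (chance share 2.86%). There were 1037 genes at an unadjusted p under 0.05. Fkbp5 had the largest panel value (1.80 ± 0.40, padj = 0.278). The count was 0 without Rat713, Rat716, Rat720, Rat726 or Rat727 and 2 without Rat722, and by setting 0 (dim genes left out, array weights, only the 2 groups or the 75th percentile as covariate) and 92 (pooled air).

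In blood at 3 h, of the B lymphocyte markers 0 of 6 were higher and 5 lower (0 and 5 over the list, padj = 0.313 with an estimated correlation), with Cd22 (-1.95 ± 0.37, padj = 0.00734), Ms4a1 (-1.73 ± 0.39, padj = 0.0146) and Cd79b (-1.52 ± 0.34, padj = 0.0146). Of the T and NK lymphocyte markers 0 of 15 were higher and 1 lower (0 and 7 over the list, padj = 0.406 with an estimated correlation), and of the neutrophil markers 1 of 9 was higher and 0 lower (1 and 1 over the list, padj = 0.406 with an estimated correlation). Their means were -0.54 and 0.52. Of the acute phase genes 1 of 21 was higher and 0 lower (2 and 1 over the list, padj = 0.0395, lost in 14 of 18 runs, up to 0.534), the 1 being the copper carrier Cp (1.69 ± 0.47, padj = 0.0342). The list mean was 0.36, beside 0.40 for kidney proximal tubule markers (2 of 9 higher), 0.33 for hepatocyte markers, 0.30 for kidney tubule injury (1 of 14 higher) and 0.29 for fibroblast markers, none of these 4 lists called. Il1r2 (2.37 ± 0.37, padj = 0.00299), the metallothionein Mt1 (1.41 ± 0.32, padj = 0.0146) and RT1-CE16 (2.35 ± 0.45, padj = 0.00776) rose. Tmbim1 (-3.14 ± 0.50, padj = 0.00299), Nup153, of the nuclear pore (-3.12 ± 0.55, padj = 0.00579), and the chaperone Hspd1 (-1.30 ± 0.31, padj = 0.0193) fell. Of the heat shock list 0 of 17 were higher and 3 lower (1 and 8 over the list, padj = 0.406). Of the respiratory chain list 0 of 26 were higher and 4 lower (0 and 8 over the list, padj = 0.406 with an estimated correlation), with Ndufb5 (-1.18 ± 0.28, padj = 0.0187). The 75th percentile of the arrays lay between 5.60 and 5.68 in the 4 exposed and between 5.83 and 5.92 in the 4 air samples (air at 1 h 5.66 to 5.77), and the median change of all genes was -0.073. Limma called 887 genes (n = 4 exposed and 4 air), 108 higher and 779 lower, 815 of them at least 2-fold. Of those called, genes higher were 74 of 247 with quantile normalization. In 10 of 11 called genes named groups did not overlap (chance share 2.86%). The count was 209 without Rat729, 245 without Rat739, 348 without Rat738 and 388 without Rat732. It was 537 without Rat730, and by setting 0 (the 75th percentile as covariate) to 310 (pooled air).

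In blood at 6 h 5 exposed samples were set against 1 air sample, Rat762, so that each difference rests on that array. Its 75th percentile was 5.67 (exposed 5.66 to 5.95, mean 5.83), and the median change of all genes was 0.084. The transferrin receptor Tfrc (3.32 ± 0.52, padj = 0.00889), Prmt9 (2.99 ± 0.55, padj = 0.0345), Yme1l1 (2.97 ± 0.41, padj = 0.00366) and Uspl1 (2.52 ± 0.40, padj = 0.00889) rose. Trim28 (2.36 ± 0.41, padj = 0.0258) and Rpp14 (2.13 ± 0.38, padj = 0.0258) rose too, and Clec3a (-2.36 ± 0.44, padj = 0.0399) fell. That sample was assumed to vary like the other blood groups, and on simulated data 0% of 2-fold changes were recovered. Limma called 7 genes (n = 5 exposed and 1 air), 6 higher and 1 lower, 7 of them at least 2-fold. In 7 of 7 called genes named, all 5 exposed lay beyond the air value (chance share 33.3%). Trim28 turned to -0.12 with pooled air. The count was 3 without Rat758, Rat760 or Rat761 and 36 without Rat789, and by setting 0 (only the 2 groups or the 75th percentile as covariate) to 118 (array weights). The 2 exposed samples at 24 h have no air sample and were not tested. Their Fkbp5 values averaged 5.81, against 5.91 in the exposed and 4.85 in the air sample at 6 h, and their Il1r2 values averaged 6.40 against 8.64 and 7.62.

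**Figure D3:**
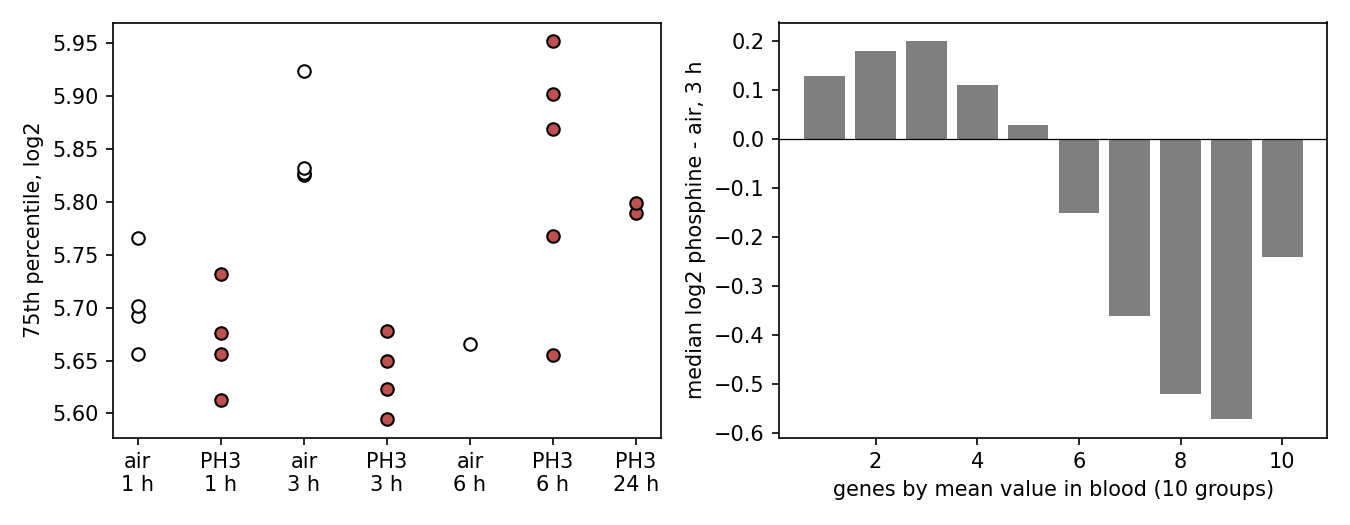
Left, 75th percentile of the log2 values of each blood array against group (points, 1 per array). Right, median log2 phosphine minus air at 3 h in 10 equal groups of genes ordered by their mean value in blood, from 0.13 in the dimmest to -0.57 in the ninth and -0.24 in the brightest group.

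The effect of exposure was compared between times within each tissue by moderated F tests, with changes in order of time. In brain it differed for 12 genes, among them Tmem252 (2.23, 1.64, 0.24 and -0.10, padj = 2.71e-05), G0s2 (-1.11, -0.73, -0.06 and 0.31, padj = 2.14e-04) and Slc2a1 (0.59, 1.02, 0.04 and -0.01, padj = 2.60e-04). In heart it differed for 57 genes, with Nr4a3 (2.46, 3.98, 0.94 and -0.46, padj = 0.00282), Irf2bp2 (1.29, 0.35, -0.53 and -0.25, padj = 0.00341) and Ky (0.29, -1.68, 0.08 and 0.14, padj = 0.00341). In kidney it differed for 235 genes, with Scarb1 (0.12, 1.33, 1.78 and -0.11, padj = 3.62e-08), Nfil3 (1.66, 0.54, -0.58 and -0.34, padj = 2.19e-06) and Slc20a1 (1.32, 1.80, 0.57 and -0.06, padj = 2.19e-06). In liver it differed for 64 genes, with Fkbp5 (0.78, 1.96, -0.09 and -0.34, padj = 2.54e-04), Srsf4 (0.66, 0.90, -0.46 and 0.03, padj = 2.76e-04) and Mrps2 (-0.12, 0.83, 0.56 and -0.41, padj = 0.00162). In lung it differed for 857 genes, with Meis1 (-1.02, -0.53, 0.07 and 0.11, padj = 7.64e-05), Bank1 (-0.86, -2.03, -0.14 and 0.35, padj = 7.64e-05) and Fbxl20 (-0.11, 0.80, -0.42 and -0.05, padj = 7.64e-05). In blood it differed for 36 genes over 1, 3 and 6 h, with Cdc73 (-0.11, -2.51 and 2.64, padj = 0.00299), Zbtb4 (0.00, -1.89 and 2.50, padj = 0.0072) and Trim28 (0.11, -1.07 and 2.36, padj = 0.0072). Their 6 h values rest on 1 air sample (Trim28 -0.12 with pooled air). By setting the counts were 22 (the mean of probe sets) and 27 (array weights) in brain, 34 (median centring) to 380 (array weights) in heart, 369 (dim genes left out) and 542 (array weights) in kidney, 42 (the other-organ arrays left out) to 199 (array weights) in liver, 1301 (array weights) in lung and 5 (quantile normalization) to 348 (array weights) in blood. The count in brain was 7 without Rat749, 22 without Rat741 and 23 without Rat729. The count in heart was 17 without Rat739, 20 without Rat763, 21 without Rat744 and 22 without Rat732, Rat745 or Rat762. It was 25 without Rat719 or Rat750, 26 without Rat733 or Rat742, 27 without Rat721 and 28 without Rat748 or Rat751. It was 29 without Rat738, 32 without Rat731 or Rat760, 35 without Rat720 and 36 without Rat712. It was 106 without Rat729 and 143 without Rat728. The count in kidney was 151 without Rat745 and 152 without Rat763. The count in liver was 36 without Rat733, 37 without Rat750 or Rat762 and 42 without Rat719 or Rat739. The count in blood was 10 without Rat760 or Rat761, 11 without Rat738, Rat739 or Rat758, 18 without Rat720 and 21 without Rat730 or Rat732. It was 22 without Rat733, 58 without Rat721, 62 without Rat713 and 68 without Rat728. It was 228 without Rat789.

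Between the 5 solid tissues, in the order brain, heart, kidney, liver and lung, the effect differed for 332 genes at 1 h, with Atf3 (-0.12, 4.16, 3.96, 0.21 and 1.87, padj = 3.02e-08), Otud1 (-0.50, 2.43, 0.15, -0.38 and -0.16, padj = 8.10e-08) and Map3k6 (0.29, 1.64, 0.31, -0.22 and 1.84, padj = 7.41e-06). At 3 h it differed for 1332 genes, with Bank1 (-0.05, 0.12, 0.08, 0.29 and -2.03, padj = 7.25e-09), Ppargc1a (0.20, 0.50, 0.44, 3.71 and -0.18, padj = 7.89e-09) and Lims2 (1.09, -0.15, -0.39, -0.82 and 1.09, padj = 7.89e-09). At 6 h it differed for 105 genes, with Abhd2 (-0.17, 2.47, 0.51, -0.24 and 0.11, padj = 7.71e-06), Klhl40 (0.46, 3.31, 0.11, 0.05 and -0.06, padj = 7.71e-06) and Got1 (0.01, 0.09, 0.38, 1.46 and 0.45, padj = 3.02e-05). At 24 h it differed for 61 genes, with Pimreg (0.07, -0.87, -0.13, 0.11 and -1.53, padj = 7.77e-08), Nmrk2 (-0.02, 3.36, -0.01, -0.11 and 0.46, padj = 5.78e-07) and Abhd1 (-0.05, 1.16, 0.05, 0.04 and -0.02, padj = 6.91e-07). With the rat as a block (pairing of tissues by animal) the counts were 411, 1375, 122 and 61, with array weights 956, 2465, 321 and 156, and with the other-organ arrays left out 223 at 6 h. Without Rat712, Rat719, Rat721 or Rat726 the 1 h count was 132, 133, 140 or 180, in that order. The 3 h count without Rat732, Rat739, Rat738 or Rat733 was 740, 750, 812 or 880. The 6 h count without Rat763, Rat762, Rat761, Rat789 or Rat760 was 11, 28, 46, 160 or 213. The 24 h count without Rat749, Rat751, Rat750 or Rat744 was 23, 24, 25 or 30. Without Rat745, Rat742, Rat748 or Rat741 it was 31, 37, 38 or 110.

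At 1 h 37 genes changed the same way in at least 3 of the 5 solid tissues, 30 higher and 7 lower, 8 of them in 4 tissues. The 10 with the largest mean absolute change all rose, with changes given for the tissues in which each was called: Atf3 (4.16 in heart, 3.96 in kidney and 1.87 in lung), Fosb (2.89 in heart, 3.27 in kidney and 3.14 in lung), Nr4a3 (2.46 in heart, 1.53 in kidney and 2.80 in lung) and Maff (1.57 in heart, 1.87 in kidney and 1.86 in lung). Next came Tmem252 (2.23 in brain, 1.54 in heart, 1.01 in kidney and 1.45 in lung), Cdkn1a (0.99 in brain, 1.13 in heart, 1.52 in kidney and 1.68 in lung) and Errfi1 (0.91 in brain, 1.19 in kidney and 1.53 in lung). They were followed by Sgk1 (1.31 in brain, 1.71 in heart and 1.03 in kidney), Pdk4 (1.65 in brain, 1.14 in heart and 1.47 in kidney) and Ifrd1 (1.66 in heart, 1.48 in kidney, 1.23 in liver and 0.89 in lung). At 3 h there were 86 such genes, 50 higher and 36 lower, 13 of them in 4 tissues and 2 in all 5. The latter were Fkbp5 (1.13 in brain, 2.0 in heart, 2.20 in kidney, 1.96 in liver and 2.83 in lung) and RT1-T24-3 (-1.68 in brain, -1.49 in heart, -1.79 in kidney, -1.56 in liver and -2.40 in lung). The other 8 of the 10 largest were Cdkn1a (0.86 in brain, 2.20 in kidney, 2.60 in liver and 1.44 in lung), Mt2A (1.34 in brain, 2.86 in heart and 2.62 in lung), Tmem252 (1.64 in brain, 1.30 in heart, 2.32 in kidney and 1.41 in lung) and Nr4a3 (3.98 in heart, 1.05 in kidney and 1.23 in lung), then Pdk4 (1.92 in brain, 1.42 in heart, 1.05 in kidney and 2.36 in lung) and RT1-N2 (-2.03 in kidney, -2.22 in liver and -1.70 in lung). The list ends with Map3k6 (1.49 in heart, 0.70 in kidney and 2.05 in lung) and Coq10b (1.10 in heart, 0.87 in kidney and 2.31 in liver). At 6 and 24 h limma gave 0 such genes. Counts at an unadjusted p under 0.05 in at least 3 tissues were 106 and 26. With the other-organ arrays left out the 1 h count was 24, and array weights gave 154 at 3 h and 1 at 6 h. Without Rat719, Rat721, Rat712, Rat720 or Rat726 the 1 h shared count was 12, 13, 16, 19 or 20, in that order. The 3 h shared count without Rat733, Rat738, Rat739, Rat730, Rat732 or Rat729 was 45, 47, 48, 49, 49 or 54.

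**Figure D4:**
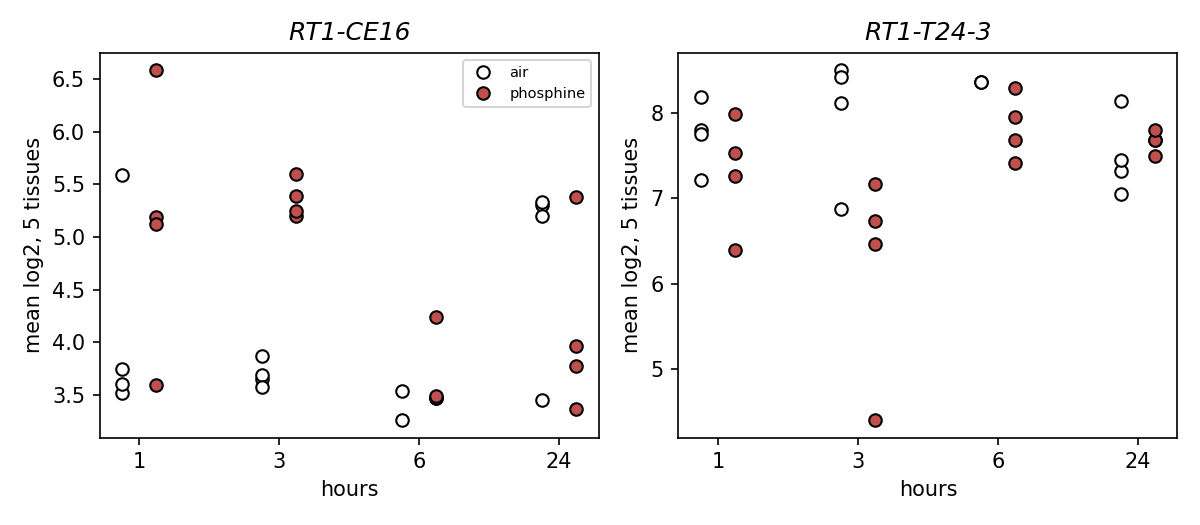
Mean log2 value over the 5 solid tissues of RT1-CE16 (left) and RT1-T24-3 (right) in each rat, against hours after exposure (points, 1 per rat, filled for phosphine and open for air). For RT1-CE16 the 4 exposed rats at 3 h lie between 5.20 and 5.60 and the 4 air rats between 3.57 and 3.87, and air rats of the other times reach 5.59.

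Over the 47 lists and 23 comparisons, camera with an estimated correlation called 17 of 1081, and a preset correlation of 0.01 added 166, and the 17 were called with both. The lists that follow, some given above for 1 comparison, were called in none, with their calls of members higher, of members lower and lowest camera adjusted p over the 23 comparisons. Of genes grouped by function, they were 7, 2 and 0.211 for metallothioneins and metal response, 11, 2 and 0.313 for endoplasmic reticulum unfolded protein response, 15, 11 and 0.193 for inflammatory cytokines, chemokines and adhesion and 1, 0 and 0.393 for interferon response. Further lists gave 3, 2 and 0.0848 for cytochrome c oxidase subunits and assembly, 9, 0 and 0.0684 for gluconeogenesis and glucose handling, 1, 3 and 0.362 for fatty acid synthesis and 8, 4 and 0.251 for cytochrome P450 and drug metabolism. Lists of iron, transmission and organ stress gave 6, 1 and 0.266 for iron and heme handling, 0, 1 and 0.373 for cholinergic genes, 15, 2 and 0.145 for cardiac stress and hypertrophy and 6, 1 and 0.186 for kidney tubule injury. Of the cell markers, they were 1, 0 and 0.087 for red blood cell markers, 0, 0 and 0.193 for cardiomyocyte markers, 3, 0 and 0.297 for skeletal muscle markers and 0, 1 and 0.429 for neuron markers. In the same order, brain cells gave 0, 2 and 0.298 for oligodendrocyte markers, 1, 2 and 0.208 for astrocyte markers, 1, 1 and 0.369 for microglia markers and 2, 0 and 0.259 for choroid plexus markers. Supporting cells and liver gave 2, 0 and 0.254 for fibroblast markers, 1, 1 and 0.266 for smooth muscle markers, 1, 0 and 0.383 for adipocyte markers and 0, 0 and 0.146 for hepatocyte markers. Kidney and lung cells gave 3, 0 and 0.211 for kidney proximal tubule markers, 2, 1 and 0.281 for distal nephron markers, 4, 2 and 0.393 for alveolar epithelium markers and 0, 0 and 0.373 for airway epithelium markers.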

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

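The tests of the arrays with transcripts of another organ, of the RT1 genes, of the white cell lists and of the picked genes and air at 1 h in blood were chosen only after the result was seen, and the 4 log2 limit for these arrays and the final reading of the 3 blood tests were set after it. The effect of exposure differed between groups by moderated F tests. Between times it differed for 12 genes in brain, 57 in heart, 235 in kidney, 64 in liver, 857 in lung and 36 in blood. Between tissues it differed for 332 genes at 1 h, 1332 at 3 h, 105 at 6 h and 61 at 24 h. Of the 35 ways to split the same rats into groups of 4, 1 (the real one) gave as many genes in 17 results. That is the smallest share 35 splits allow, and it was not adjusted over the results. Read 1 at a time, the share argues against chance for results other than lung 24 h, but 35 splits are too few to exclude it. In lung at 24 h 3.16% of genes had an unadjusted p under 0.05, and the count was 0 without Rat742, Rat744, Rat748, Rat749, Rat750 or Rat751. With the real count and the highest of the other splits, the 17 results are brain 3 h (68, 6), heart 1 h (179, 11), heart 3 h (448, 121), heart 24 h (11, 1), kidney 1 h (419, 297), kidney 3 h (859, 3), liver 1 h (45, 0), liver 3 h (518, 1), lung 1 h (779, 246), lung 3 h (1559, 127), lung 24 h (1, 0), blood 3 h (887, 1), between tissues at 1 h (332, 11), between tissues at 3 h (1332, 63), between tissues at 24 h (61, 43), shared at 1 h (37, 0) and shared at 3 h (86, 0). The kidney 1 h count and the 24 h count between tissues lay nearest their highest other split, and the kidney count was 193 without Rat719, 209 without Rat721 and 245 without Rat720. The bound was not met for brain 1 h, where 2 of 35 splits gave as many (real count 20). There the split of Rat710, Rat721, Rat726 and Rat727 from the rest called 138, several times the real count, which points to a structure of these samples. The bound was not met for blood 1 h either, where 9 of 35 splits gave as many (1, highest other 40). Limma counts of 0 at 24 h, in brain, kidney, liver (3.79%, 5.5% and 7.14% of genes at an unadjusted p under 0.05) and shared (26 genes), can tell nothing by splits, since any split has as many (35 of 35, highest others 8, 1, 5 and 0).

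In 41 of 710 groups of 4 or 5 samples behind the printed genes, 1 sample lay far from the others by Dixon's ratio, its gap to the nearest over the range of the group. Chance gives about 1 in 20 groups, or 35.5 here. In brain at 3 h it was Bank1 0.851 (air Rat738). In heart at 1 h it was Nr4a3 0.843 (air Rat721), Cxcr4 0.84 (air Rat727), Ky 0.884 (air Rat727), Otud1 0.848 (air Rat721), Maff 0.941 (air Rat720) and Cdkn1a 0.92 (air Rat721). At 3 h it was Hs3st5 0.852 (Rat728). At 24 h it was Pimreg 0.869 (air Rat751) and Abhd1 0.864 (air Rat745). In kidney at 1 h it was Fosb 0.931 (air Rat721) and Maff 0.91 (air Rat720). At 3 h it was Fkbp5 0.921 (Rat729), Hmox1 0.901 (air Rat738) and Slc20a1 0.895 (Rat729). At 24 h it was Pimreg 0.872 (Rat749). In liver at 1 h it was Ppargc1a 0.905 (air Rat721), Coq10b 0.867 (air Rat726), Osgin1 0.886 (air Rat727), Srsf4 0.909 (Rat716), Nr4a3 0.933 (air Rat720), Nr4a3 0.84 (Rat719) and Sgk1 0.867 (Rat712). At 3 h it was Sds 0.97 (air Rat732). At 6 h it was Txnrd3 0.851 (Rat789). In lung at 1 h it was Crem 0.857 (air Rat721), Atf3 0.864 (Rat716) and Bank1 0.916 (Rat716). At 3 h it was Pdk4 0.892 (air Rat733), Pglyrp1 0.943 (Rat728), RT1-T24-3 0.863 (Rat729), Lims2 0.838 (Rat729), Cdkn1a 0.934 (Rat730) and Nr4a3 0.832 (air Rat738). At 24 h it was Nmrk2 0.834 (air Rat744). In blood at 3 h it was Ms4a1 0.934 (air Rat733), Cd79b 0.972 (air Rat733), Tmbim1 0.836 (air Rat733), Cdc73 0.834 (air Rat739) and Trim28 0.973 (Rat731). At 6 h it was Zbtb4 0.747 (Rat789).

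On 10 arrays a marker list of another organ or of muscle lay at least 4 log2 above the median of the tissue. Against a response to the exposure, the 12 other exposed arrays of the 4 groups with raised hepatocyte markers reached 1.34 at most, and 2 of the 10 arrays were of air rats. RNA of the other organ in the sample may account for 6 of the 7 arrays with a named organ, where 97.6% to 100% of genes at least 6 log2 higher in that organ were raised by over 1 log2, and in the heart of Rat729 Alb stood at 13.95 against 5.57 in its group and 14.12 in liver. In the heart of Rat760 it was 56.8%, between the bounds of 50% and 90%, with Alb at 12.20, so that there it cannot be told apart from another source. Under the limit, the hepatocyte markers of both air hearts at 6 h also stood high, at 3.04 (Rat762) and 3.21 (Rat763) above the heart median. Of the 9 hepatocyte markers, heart and lung express 2 and kidney 4 above the median of all probe sets, and the 3 arrays with muscle transcripts have no organ of comparison and were not tested.

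Of 18 RT1 and related H2 genes, 7 were called in at least 1 solid tissue at 3 h, and RT1-T24-3 in all 5. An inherited difference between animals of this outbred stock may account for them, since in 14 air rats the median correlation of a rat's deviation between tissues was 0.57 (Pearson, Spearman 0.48, one-sided permutation p = 1e-05 for each, the smallest that 100000 permutations give). Over all genes the median was 0.03 and the 95th percentile 0.32, and without air Rat726 and Rat751, farthest from the median, it was 0.49, just under the bound of 0.5. A response to phosphine cannot be told apart from it, because the range among air rats was 1.19 times the 3 h difference (median of the 7 genes), between the bounds set. RT1-T24-3 averaged 4.40 in Rat729 over 5 tissues, against 6.47 to 7.17 in the other exposed and 6.88 to 8.50 in the air rats at 3 h.

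In blood at 3 h, 779 of 887 called genes were lower. The spread of values (75th percentile) was narrower on the 4 exposed arrays. Quantile normalization within blood, which equalizes spreads, left 27.8% of the number, within the bound set before for that explanation. The 779 genes all kept lower estimates (median -1.16, SE 0.35, against -1.44, SE 0.36), but were picked on these arrays, so this cannot decide. The spread may account for many calls, yet 173 still called lower argue against it as the whole cause. A uniformly lower share of white cell RNA is weakly argued against. The neutrophil list averaged 0.52 (9 genes, SE 0.28) and the B lymphocyte list -1.25 (6 genes). They lay 1.77 apart (SE between arrays 0.37), but were picked as extremes of 4 lists. The T and NK list averaged -0.54 (SE 0.18) and the monocyte list -0.12 (SE 0.16), none of the 4 passed camera, and a fall of lymphocytes stays open. Air arrays of 3 h that stand apart from the other air arrays cannot be told apart from a response. Their 75th percentile lay above air at 1 h (5.66 to 5.77) and 6 h (5.67, 1 array). Air at 1 h against air at 3 h called 8 genes, 0.9% of the number, under the bound set before. That bound on calls cannot decide, since the exposed arrays called 2 genes against air at 1 h (11.45% at an unadjusted p under 0.05). In 6 picks, genes chosen against 2 of the 3 h air arrays were read against the other 2. Air at 1 h lay from -0.70 to -0.47 (median of all genes -0.10 to -0.06). Phosphine lay from -1.43 to -1.18, enlarged as its arrays made the pick. With the 75th percentile as covariate limma called 0 genes (5.87% at an unadjusted p under 0.05, median of the 779 genes -0.65, SE 0.48), where covariate and group nearly overlap and the SE grew.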

How the results depend on the processing

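Leaving out the 10 arrays with transcripts of another organ, the 75th percentile covariate, and leaving out rats for the tests of differences and shared genes were chosen only after the result was seen. Among 708 pairs of a named gene and a comparison, 640 kept direction and side of the threshold under quantile normalization, 649 under median centring, 660 with the mean of probe sets, 691 with trended robust eBayes, 655 with array weights, 386 with only the 2 groups, and 581 with pooled air. With dim genes left out 581 of 586 did, without the other-organ arrays 475 of 566, with the covariate 18 of 77, and without a rat 4162 of 5427 values. The 1 reversal was Trim28 in blood at 6 h, -0.12 with pooled air. Of 1081 list tests 17 were called, and calls were gained 28 times in other settings, 13 times without a rat and 166 times with a preset correlation, 0 with a reversed direction. Of the 50 genes named for a difference, 49 kept their call with the mean of probe sets and each of those tested in the other settings, apart from 2 of 1005 values without a rat. Of 20 shared genes 15 of 18 did with dim genes left out and 18 without the other-organ arrays, 19 with trended eBayes or array weights, 20 with quantile normalization, median centring or the mean of probe sets, and 135 of 160 values did without a rat. Counts of genes at least 2-fold moved by over 1.5 times in 14 of 23 comparisons with pooled air, 13 with only the 2 groups and 10 with array weights. Only 2 groups leave fewer arrays to estimate the spread, and pooled air gives more controls. The cause of a moved count was not tested in any setting. With the rat as a block, the counts between tissues stayed within 1.5 times. How far signal over background limits dim genes was tested only by leaving them out.

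With quantile normalization within tissue, gene counts were 7 (lung 6 h) and 247 (blood 3 h). Counts between times were 5 (blood). List adjusted p-values were 0.0717 (ATF4 kidney 1 h), 0.0591 (immediate early kidney 1 h), 0.0995 (ATF4 lung 1 h), 0.0793 (clock lung 24 h, cell cycle lung 24 h, T and NK lung 24 h) and 0.0657 (acute phase blood 3 h).

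With array median centring, gene counts were 7 (liver 6 h) and 8 (lung 6 h). Between times, the counts were 34 (heart) and 15 (blood). For lists, adjusted p-values were 0.0504 (ATF4 kidney 1 h), 0.146 (ATF4 liver 1 h), 0.103 (glucocorticoid liver 1 h), 0.245 (ATF4 lung 1 h), 0.0757 (clock lung 24 h, T and NK lung 24 h) and 0.0518 (acute phase blood 3 h).

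With dim genes left out, gene counts were 34 (brain 1 h), 54 (liver 6 h), 23 (lung 6 h), 0 (blood 1 h) and 35 (blood 6 h). Time differences were 369 (kidney), 104 (liver) and 68 (blood). Adjusted p-values of lists were 0.245 (macrophage heart 24 h), 0.0761 (ATF4 kidney 1 h, immediate early kidney 1 h), 0.066 (ATF4 lung 1 h), 0.0613 (coagulation lung 1 h), 0.194 (clock lung 24 h), 0.166 (cell cycle lung 24 h, T and NK lung 24 h) and 0.37 (acute phase blood 3 h).

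With the mean of probe sets per gene, gene counts were 3 (brain 6 h), 19 (heart 24 h) and 0 (lung 24 h). Genes that differ between times were 22 (brain). Among lists, adjusted p-values were 0.0732 (ATF4 liver 1 h) and 0.135 (acute phase blood 3 h).

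With trended robust eBayes, gene counts were 20 (heart 24 h), 50 (liver 6 h) and 45 (blood 6 h). Counts between times were 101 (blood).

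With array quality weights, gene counts were 382 (brain 1 h), 150 (brain 3 h), 277 (heart 1 h), 560 (heart 6 h), 260 (heart 24 h), 243 (kidney 1 h), 453 (kidney 6 h), 135 (liver 1 h), 1007 (liver 3 h), 65 (liver 6 h), 3 (lung 6 h), 8 (lung 24 h), 0 (blood 1 h) and 118 (blood 6 h). Between times, the counts were 27 (brain), 380 (heart), 542 (kidney), 199 (liver), 1301 (lung) and 348 (blood). Counts between tissues were 956 (1 h), 2465 (3 h), 321 (6 h) and 156 (24 h). Shared counts were 154 (3 h) and 1 (6 h). List adjusted p-values were 0.279 (ATF4 lung 1 h), 0.0947 (clock lung 24 h, T and NK lung 24 h), 0.0883 (cell cycle lung 24 h) and 0.0632 (acute phase blood 3 h).

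With only the 2 groups in the fit, gene counts were 1 (brain 1 h), 2 (brain 6 h), 51 (heart 1 h), 13 (heart 3 h), 4 (heart 6 h), 0 (heart 24 h, liver 6 h, lung 6 h, blood 1 h, blood 6 h), 39 (kidney 1 h), 463 (kidney 3 h), 7 (kidney 6 h), 8 (liver 1 h), 260 (liver 3 h), 132 (lung 1 h) and 11 (lung 24 h). For lists, adjusted p-values were 0.369 (glucocorticoid brain 3 h), 0.241 (endothelium brain 3 h), 0.425 (ATF4 heart 1 h), 0.152 (immediate early heart 1 h), 0.29 (glucocorticoid heart 1 h), 0.364 (coagulation heart 1 h), 0.254 (macrophage heart 24 h), 0.0746 (ATF4 kidney 1 h, immediate early kidney 1 h), 0.102 (ATF4 liver 1 h, glucocorticoid liver 1 h), 0.278 (ATF4 lung 1 h), 0.194 (coagulation lung 1 h), 0.622 (clock lung 24 h), 0.247 (T and NK lung 24 h) and 0.498 (acute phase blood 3 h).

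With air of all times pooled, gene counts were 218 (brain 1 h), 20 (brain 6 h), 547 (heart 1 h), 1072 (heart 3 h), 794 (heart 6 h), 91 (heart 24 h), 1777 (kidney 3 h), 1676 (kidney 6 h), 243 (liver 1 h), 974 (liver 3 h), 969 (liver 6 h), 1831 (lung 1 h), 429 (lung 6 h), 0 (lung 24 h), 92 (blood 1 h), 310 (blood 3 h) and 34 (blood 6 h). Adjusted p-values of lists were 0.35 (endothelium brain 3 h), 0.0583 (immediate early kidney 1 h), 0.213 (ATF4 liver 1 h), 0.921 (clock lung 24 h), 0.227 (cell cycle lung 24 h, T and NK lung 24 h) and 0.534 (acute phase blood 3 h).

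Without the arrays carrying transcripts of another organ, gene counts were 276 (heart 3 h), 211 (heart 6 h), 22 (heart 24 h), 245 (kidney 1 h), 9 (liver 1 h) and 23 (lung 6 h). Time differences were 114 (heart) and 42 (liver). Between tissues, the counts were 223 (6 h). Shared genes were 24 (1 h). Among lists, adjusted p-values were 0.0865 (ATF4 heart 1 h), 0.0677 (immediate early heart 1 h, glucocorticoid heart 1 h), 0.0771 (coagulation heart 1 h), 0.108 (macrophage heart 24 h), 0.122 (ATF4 liver 1 h), 0.0562 (glucocorticoid liver 1 h), 0.254 (ATF4 lung 1 h), 0.0723 (clock lung 24 h, cell cycle lung 24 h) and 0.101 (T and NK lung 24 h).

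With the 75th percentile of the array as covariate, gene counts were 0 (blood 1 h, blood 3 h, blood 6 h). List adjusted p-values were 0.14 (acute phase blood 3 h).

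Leaving out 1 rat at a time, gene counts were 9 to 70 (brain 1 h), 40 to 76 (brain 3 h), 0 to 3 (brain 6 h), 73 to 199 (heart 1 h), 187 to 1099 (heart 3 h), 3 to 57 (heart 6 h), 4 to 32 (heart 24 h), 193 to 604 (kidney 1 h), 3 to 52 (kidney 6 h), 9 to 47 (liver 1 h), 308 to 510 (liver 3 h), 0 to 58 (liver 6 h), 913 to 1365 (lung 3 h), 3 to 39 (lung 6 h), 0 to 2 (lung 24 h), 0 to 2 (blood 1 h), 209 to 960 (blood 3 h) and 3 to 36 (blood 6 h). Genes that differ between times were 7 to 23 (brain), 17 to 143 (heart), 151 to 327 (kidney), 36 to 93 (liver) and 10 to 228 (blood). Tissue differences were 132 to 342 (1 h), 740 to 1496 (3 h), 23 to 110 (24 h) and 11 to 213 (6 h). Shared counts were 12 to 45 (1 h) and 45 to 115 (3 h). For lists, the lowest adjusted p with 1 rat left out is given, then each with which the call ended. Glucocorticoid brain 3 h gave 0.00651, then 0.0501 (Rat739). ATF4 heart 1 h gave 0.0139, then 0.0645 (Rat712), 0.062 (Rat719), 0.0763 (Rat720), 0.0553 (Rat726) and 0.134 (Rat727). Immediate early heart 1 h and glucocorticoid heart 1 h gave 0.0139, then 0.0726 (Rat727). Coagulation heart 1 h gave 0.0139, then 0.0645 (Rat712), 0.062 (Rat719), 0.0763 (Rat720), 0.0577 (Rat721) and 0.111 (Rat727). Macrophage heart 24 h gave 0.017, then 0.151 (Rat741), 0.1 (Rat742), 0.071 (Rat745), 0.0601 (Rat749) and 0.0939 (Rat750). ATF4 kidney 1 h gave 0.0219, then 0.12 (Rat710), 0.0638 (Rat712), 0.064 (Rat726) and 0.069 (Rat727). Immediate early kidney 1 h gave 0.0228, then 0.0929 (Rat710), 0.0638 (Rat712), 0.0514 (Rat716), 0.0747 (Rat726) and 0.069 (Rat727). ATF4 liver 1 h gave 0.0321, then 0.0729 (Rat719) and 0.119 (Rat726). Glucocorticoid liver 1 h gave 0.0153, then 0.0546 (Rat721) and 0.0519 (Rat726). ATF4 lung 1 h gave 0.0123, then 0.283 (Rat716), 0.094 (Rat719), 0.104 (Rat720) and 0.114 (Rat727). Clock lung 24 h gave 0.0325, then 0.0613 (Rat741), 0.0755 (Rat742), 0.0576 (Rat748), 0.182 (Rat749), 0.146 (Rat750) and 0.215 (Rat751). Cell cycle lung 24 h gave 0.0383, then 0.0823 (Rat741), 0.0755 (Rat742), 0.0558 (Rat745), 0.0576 (Rat748), 0.116 (Rat749), 0.146 (Rat750) and 0.108 (Rat751). T and NK lung 24 h gave 0.0383, then 0.0823 (Rat741), 0.0869 (Rat742), 0.065 (Rat744), 0.183 (Rat749), 0.146 (Rat750) and 0.142 (Rat751). Acute phase blood 3 h gave 0.0154, then 0.0738 (Rat728), 0.0528 (Rat730), 0.164 (Rat731), 0.0837 (Rat732), 0.118 (Rat733) and 0.0523 (Rat739).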

Other observations

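The 5 further random draws were chosen only after the result was seen, as was a tighter bound for exclusion. Some genes differed between rats in the same way in all 5 solid tissues, whether the rat inhaled phosphine or air. Of the 50 genes whose deviations from the group mean went together most between tissues over 30 rats, the first 4 were Retsat, a retinol saturase, Ephx2, an epoxide hydrolase, Pxmp4 of peroxisomes and Fam111a. None of these 4 was called in a tissue at 1 or 3 h, while RT1-T24-3, the sixth, was called in all 5 tissues at 3 h.

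An inherited difference between rats of an outbred stock is a candidate explanation, and it would place more of the 50 genes beside each other on a chromosome than chance does if it came in blocks of neighbours. Of the 50 genes 2 had another of the 50 within 10 genes, where 4979 of 10000 random sets had as many and the 95th percentile was 4. The random median was 0 in that draw and 2 in each of 5 others, and at 2 the count meets the bound set before for excluding the explanation, though not beyond its spread. Neighbours were not beyond chance, yet a variant of a single gene needs no neighbour, so that inheritance cannot be told apart from another lasting difference between animals.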
